A study of Mus musculus with 82 samples.

How the data were processed

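The deposited peak lists of 4 ChIP-seq constructs and the authors' merged list were analysed. Per the labels, the constructs were EoGFP and BraGFP (2 libraries each with doxycycline) and EoV5 and EoVP16 (1 library each with doxycycline), in mouse cells lacking Eomes and Brachyury. Libraries without doxycycline, the input, H3K27ac, ATAC-seq and RNA-seq were not analysed here. Samples were grouped by construct and treatment as the titles give them, and peak lists were joined to samples through the labels.

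Per the submitters' processing notes, Bowtie2 2.3.4, Picard 1.56.0, SAMtools 1.3.1, MACS2 2.1.1.20160309.4, bedtools 2.27.0 and deepTools 3.0.2 were used with the mouse build mm10/GRCm38. The notes do not give their order or settings. The deposited EoGFP, BraGFP and merged lists hold positions and names only, with no height or score. The deposited EoV5 and EoVP16 lists have no header, and their column order is that of a MACS2 table. In these deposited lists, signal is the pileup at the summit, in fragments, written as whole numbers and not scaled to depth as far as the values show. The authors' lists also give the −log10 p and −log10 q of each peak (neg_log10_p) against the caller's background, which were not used here. The deposited ratio is the fold enrichment at the summit over the background estimated by the caller. The minimum pileups of 120, 40, 60 and 36 come from the names of the deposited files. How the 2 libraries of EoGFP and of BraGFP were joined, and which control was used, is not stated.

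The depth of the libraries is not given by these files, so no value is scaled to depth. The number in the peak names ran to 230846 in EoGFP, of which the list held 13.1%, and to 129722 in BraGFP (21.3%), 181083 in EoV5 (21.1%) and 129604 in EoVP16 (28.0%). Peaks on unplaced contigs were left out (4, 7, 7 and 6), as were repeated entries (12, 4, 46 and 26), leaving 21 assembled chromosomes. Width stood in for height where a list held none, and Spearman's rho between width and pileup over peaks was 0.312 in EoV5 and 0.471 in EoVP16.

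Peaks were called overlapping when they shared at least 1 bp. EoGFP-only and BraGFP-only are peaks of one list with no overlap in the other, and EoV5-only and EoVP16-only are defined likewise. Overlap was tested against 1000 circular shifts of one list along each chromosome, one-sided for overlaps and two-sided for location. At equal list size, the 13000 widest peaks of each list were compared by the exact McNemar test over the peaks of the shared list, with p printed no lower than 1e-300. Differences of medians were tested by 100000 permutations over peaks. Shares carry 95% Wilson intervals and pileups carry exact 95% Poisson intervals.

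Genes came from a GRCm38 gene table with 21887 coding genes. The design planned distances to the transcription start, but the table gives no strand or exons. Distances were measured from the peak midpoint to the gene span, and location was split into within 1 kb of either end of a coding gene, elsewhere inside one, and outside. The number of members with a peak midpoint within 50 kb was compared with 10000 random lists matched on the decile of gene territory, and adjusted by Benjamini-Hochberg over 84 tests (21 lists in 4 peak lists). Of the 21 lists, 14 were tested programmes, 3 were other cell types and 4 were unrelated controls. EoGFP-only against BraGFP-only peaks near each list were compared by Fisher's exact test, two-sided, adjusted over the 21 lists. For random runs, members whose 50 kb windows touch formed a locus. A run started at a coding gene of the same territory decile as the first member of the locus and took genes at the same ranks along the chromosome. One epiblast name, Oct6, had no match in the table.

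Named genes followed a rule fixed before the data were examined. It took the 7 factors put back into the double knockout, the 3 members of each tested list with the most EoGFP plus BraGFP peaks within 50 kb, the genes nearest to the 5 widest peaks of each class, and the 5 genes with the most peaks in EoGFP and in BraGFP. Width replaced the planned height in this rule, and it gave 65 genes. Genes outside it were chosen after their values were seen: the list members with peaks of one factor alone, the Hox genes Hoxa3 and Hoxb13, and the genes at the tallest EoV5 and EoVP16 peaks.

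Tests and alternatives were fixed before the data were examined, except those described as added. Alternatives covered the overlap rule, the wider or taller 50% of each list, autosomes, list size, ranking, windows of 10 and 100 kb, a distance of 5 kb, and random lists without matching. The motif and half-site comparisons of the design need a genome sequence, which was not used here, and were not run. Added after seeing the data were ranking by pileup, thinning to 27588 peaks, EoV5 height in place of width, peak counts near gene lists (once per gene, or once per peak with random runs), matched random lists and random runs for the differences, the EoV5 and EoVP16 comparison at gene lists, restriction to peaks held or not held by the other Eomes lists, differences of location between classes, division of the lists into 10 parts by pileup, tests of single Hox clusters, and other windows for named genes.

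The functions were tested on simulated data. A planted overlap of 30.1% was returned as 30.1%, 2% of 100 pairs of independent lists passed the threshold, and random cases passed at 2.14% for gene lists and 1.52% for differences. The simulated peaks were not clustered, whereas peaks in these lists are. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.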

Results

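The series holds 82 mouse samples, of which 66 are RNA-seq, 12 are ChIP-seq and 4 are ATAC-seq libraries. The peak lists of 4 tagged T-box proteins are described here, and the RNA-seq, ATAC-seq and H3K27ac libraries were not used here. Per the labels, the ChIP-seq cells carried a knockout of both Eomes and Brachyury (dKO), held 1 construct induced by doxycycline, and were taken on day 5 of differentiation with activin A at 30 ng/ml. Eomes and Brachyury (gene symbol T) are T-box transcription factors of the primitive streak, the structure from which mesoderm and definitive endoderm arise. EoGFP and BraGFP are Eomes and Brachyury with a GFP tag, EoV5 is Eomes with a V5 tag, and EoVP16 is Eomes joined to the VP16 activation domain.

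The EoGFP list held 30129 peaks and the BraGFP list 27588, each a single peak set standing for 2 libraries. The EoV5 list held 38193 peaks and the EoVP16 list 36203, each from 1 library. The deposited lists were kept above a minimum pileup (height in fragments) that differed between them, 120 for EoGFP, 40 for BraGFP, 60 for EoV5 and 36 for EoVP16 per the file names. Median peak width was 871 bp for EoGFP (interquartile range 644 to 1220), 587 bp for BraGFP (418 to 875), 820 bp for EoV5 (571 to 1247) and 793 bp for EoVP16 (536 to 1237). EoV5 peaks had a median pileup of 99 fragments (interquartile range 75 to 156) and a median fold enrichment of 14.1. EoVP16 peaks had a median pileup of 54 fragments (43 to 73) and a median fold enrichment of 9.02. With 1 peak set per construct there are no replicate values, the read depth of the libraries is unknown from these files, and every test below describes these lists. Intervals are 95% Wilson intervals unless named otherwise and cover counting error only.

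The comparison of EoGFP with BraGFP asked how far the 2 factors occupy the same sites. At Mesp1, a bHLH factor of early cardiac mesoderm, 3 of 8 EoGFP peaks within 50 kb overlapped BraGFP peaks. At Nanog, a pluripotency factor, 3 of 7 EoGFP peaks did. At Pou3f1, a POU factor of epiblast and early neural tissue, the count was 3 of 8. Over the genome, 8083 of 27588 BraGFP peaks overlapped an EoGFP peak, or 29.3% (28.8 to 29.8). In the other direction, 8152 of 30129 EoGFP peaks overlapped a BraGFP peak, or 27.1% (26.6 to 27.6). Shifting one list along each chromosome gave means of 2.08% and 1.91%, so the measured shares were 14.1 and 14.2 times higher. Both had p = 0.001 in a one-sided permutation test, the smallest value that 1000 shifts can give. Shifts do not keep peaks near genes: 42.9% of shared peaks lay within 1 kb of a coding gene's end, against 3.17% in the shifts. The excess over shifts, here and in the overlaps below, therefore does not separate sites specific to the 2 proteins from a common preference for such positions. Of the wider 50% of BraGFP peaks, 44.6% overlapped a peak of the whole EoGFP list and 35.0% one of its wider 50%. The authors' merged list joins these 2 lists, so its split follows from them and is no separate result. Of its 49484 regions on assembled chromosomes, 21977 (44.4%) held EoGFP only, 19505 (39.4%) BraGFP only and 8002 (16.2%) both.

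**Figure D1:**
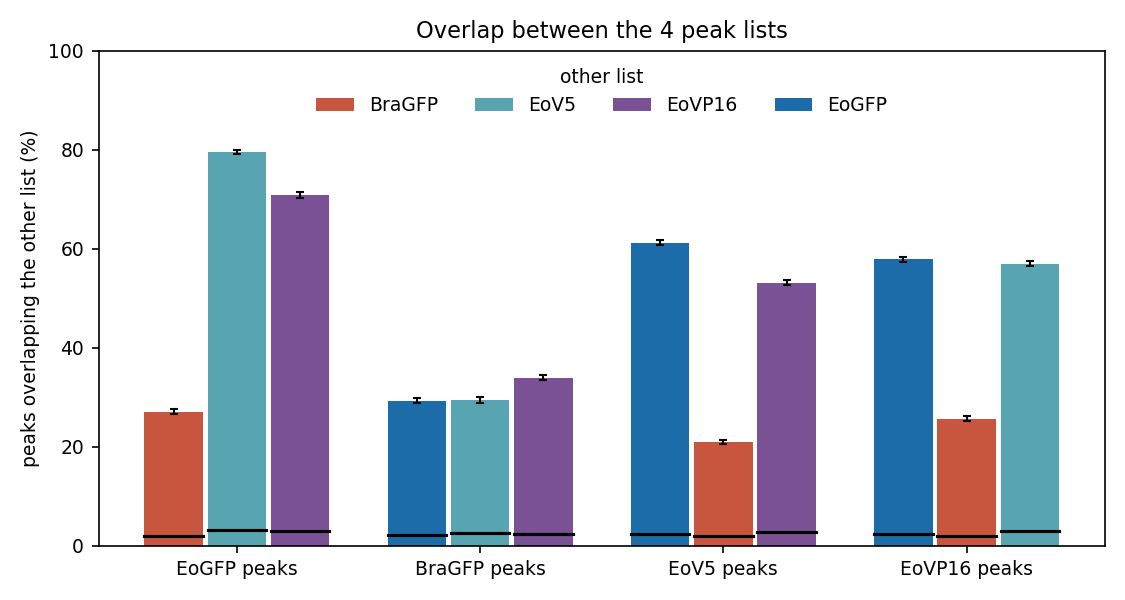
Share of the peaks of each list (x axis) that overlap each other list by at least 1 bp, in percent (y axis), with bar colour giving the other list. Error bars are 95% Wilson intervals and black lines are the mean of 1000 circular shifts; EoGFP peaks overlap EoV5 at 79.6% and BraGFP at 27.1%, all above the shifted means.

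The 7 factors that the study put back into the double knockout were bound in different patterns. Mixl1, a homeobox gene of the primitive streak, had 5 EoGFP, 6 EoV5 and 5 EoVP16 peaks within 50 kb and 0 BraGFP peaks, although 4 BraGFP peaks lay within 100 kb. Msgn1, a bHLH factor of presomitic mesoderm, had 6 BraGFP and 2 EoGFP peaks. Both EoGFP peaks of Msgn1 were shared with BraGFP, and 4 of its BraGFP peaks overlapped no EoGFP peak. Foxa2, a forkhead factor of endoderm and notochord, had 6 EoGFP, 2 BraGFP, 9 EoV5 and 5 EoVP16 peaks. Six2, a homeobox gene known from kidney progenitors, had 6 EoGFP peaks and 1 BraGFP peak.

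Near Mixl1 (GRCm38 chromosome 1, 180693043 to 180697034), an EoGFP peak at 180696354 to 180697779 covered one end of the gene. The EoV5 peak there (180696330 to 180698214) had a pileup of 273 fragments (95% Poisson interval 242 to 307) and the EoVP16 peak (180696235 to 180697724) a pileup of 72 (56.3 to 90.7). The tallest EoV5 peak of Mixl1 lay 4.53 kb outside the other end of the gene, at 180688223 to 180688814, with 340 fragments (305 to 378). At Msgn1 (chromosome 12, 11208382 to 11208948), the widest BraGFP peak was 1820 bp long, at 11208402 to 11210221, and it covered most of the gene and ran past one end. No EoGFP, EoV5 or EoVP16 peak overlapped it. All 4 lists held a peak 30.1 to 30.7 kb from Msgn1, where the EoV5 peak (11177028 to 11179022) had 452 fragments (411 to 496).

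Eomes itself (chromosome 9, 118478186 to 118486132) had 6 EoGFP and 4 BraGFP peaks within 50 kb, of which 2 EoGFP peaks were shared. An EoGFP peak at 118486320 to 118488643 lay 1.35 kb outside one end of Eomes, and 0 BraGFP peaks lay within 10 kb of the gene. T (chromosome 17, 8434423 to 8442496) had 4 EoGFP and 5 BraGFP peaks, of which 1 EoGFP peak was shared. Mesp1 (chromosome 7, 79792241 to 79793590) had an EoGFP peak over the gene, at 79792282 to 79793774. The tallest EoV5 peak of Mesp1 (79796301 to 79798218, 211 fragments, 183 to 241) lay 3.67 kb from the gene and was matched by peaks in the other 3 lists. The peaks near these genes were not tested gene by gene, and the counts depend on the window and on the minimum pileup of each list.

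**Figure D2:**
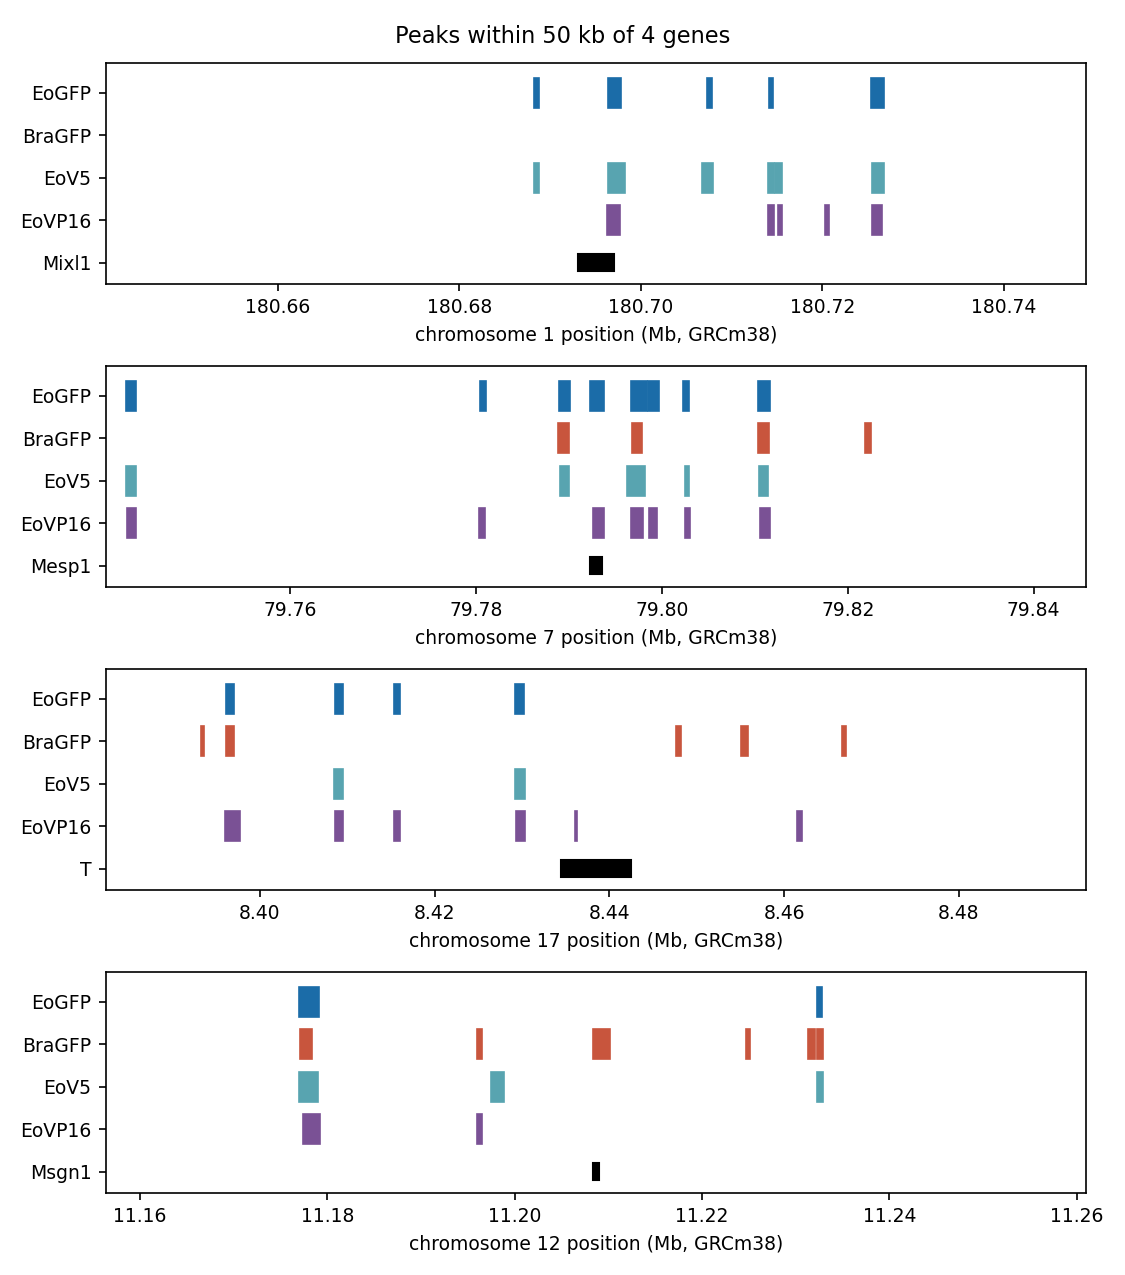
Peaks of the 4 lists within 50 kb of Mixl1, Mesp1, T and Msgn1, drawn as boxes along the chromosome (x axis, Mb, GRCm38), with the gene as a black box. Mixl1 has 5 EoGFP and 0 BraGFP peaks in this window, and Msgn1 has 2 EoGFP and 6 BraGFP peaks.

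Shared peaks were wider than unshared ones. EoGFP peaks with a BraGFP peak had a median width of 1080 bp against 814 bp without, a difference of 266 bp. BraGFP peaks with an EoGFP peak had a median of 875 bp against 515 bp, a difference of 360 bp. Both differences had p = 1e-05 in a two-sided permutation test over peaks, the smallest that 100000 permutations can give. The height of EoV5 peaks depended on the side compared. At EoGFP sites, EoV5 peaks had a median of 113 fragments with BraGFP (n = 6673) and 130 without (n = 16699), a difference of -17 (permutation p = 1e-05, the smallest possible). At BraGFP sites found in EoV5, the median was 113 with EoGFP (n = 6685) and 87 without (n = 1438), a difference of 26 (permutation p = 1e-05, the smallest possible). These comparisons were added after the lists were seen to hold no height for EoGFP and BraGFP.

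The widest shared peak, 7112 bp long, lay at chromosome 9, 61367706 to 61374817, over one end of Tle3, which encodes a Groucho-type corepressor. The next widest lay 70570 bp from Kcnrg, at the protocadherin gene Pcdh7, at Sin3a, which encodes a corepressor scaffold, and near Dusp4, a MAP kinase phosphatase. The widest EoGFP-only peak, 6467 bp long, lay at chromosome 8, 84659810 to 84666276, over Ier2, an immediate early gene, and the others at Esrp2, Plec, Hs3st3b1 and Nectin2. The widest BraGFP-only peak, 5525 bp long, lay at chromosome 17, 34118577 to 34124101, at Brd2, which encodes a bromodomain protein, and the others nearest to Pigv, Cubn, Gng2 and Bhlhe40. The genes with most EoGFP peaks within 50 kb were the long genes Auts2 (28), Nav2 (24), Arhgap26 (23), Bcas3 (22) and Camta1 (22). Those with most BraGFP peaks were Auts2 (29), Atxn1 (26), Maml2 (24), Ptprg (24) and Tenm4 (24), and Auts2 spans 1106 kb.

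The overlap of EoGFP with EoV5 asked how far 2 tags gave the same Eomes sites. Peak counts near genes were close in places and apart in others: EoGFP and EoV5 each had 10 peaks at Lef1, a transcription factor of the Wnt pathway, but 8 and 3 at Pou3f1, 5 and 10 at Gata4 and 6 and 17 at Pcdh7. In all, 79.6% of EoGFP peaks (79.1 to 80.0) overlapped an EoV5 peak, and 61.2% of EoV5 peaks (60.7 to 61.7) overlapped an EoGFP peak. Shifts gave means of 3.08% and 2.41% (permutation p = 0.001, the smallest possible). With both lists cut, to the wider 50% of EoGFP and the taller 50% of EoV5, the shares were 50.3% and 38.9%. Cutting the partner list lowers such shares by itself, so these values do not show less overlap at strong peaks. The share depended on EoV5 height. Of the tallest 3819 EoV5 peaks (272 to 3296 fragments), 96.3% (95.6 to 96.8) overlapped EoGFP, and of the lowest 3820 (61 to 66 fragments), 32.8% (31.3 to 34.3) did. This division of the lists by height was chosen after seeing the data.

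EoVP16 was compared with EoV5, both pulled down through V5, to ask whether the activator fusion occupies the sites of full-length Eomes. At Foxa2 (chromosome 2, 148042877 to 148046969), both had a peak over one end of the gene, with 336 fragments in EoV5 (301 to 374) and 152 in EoVP16 (129 to 178). At Lef1 both lists held 10 peaks. Snai1, a repressor active in epithelial-mesenchymal transition, had 5 EoV5 and 11 EoVP16 peaks, and Zeb2, a factor of the same process, had 11 and 18. Pcdh7 had 17 EoV5 and 10 EoVP16 peaks. Over the genome, 56.9% of EoVP16 peaks (56.4 to 57.5) overlapped EoV5, and 53.1% of EoV5 peaks (52.6 to 53.6) overlapped EoVP16. The shifted lists gave 3.02% and 2.85% (permutation p = 0.001, the smallest possible). Of the tallest 3620 EoVP16 peaks, 97.4% (96.8 to 97.8) overlapped EoV5, and of the lowest 3621, 28.7% (27.3 to 30.2) did. Over the 20280 EoV5 peaks that overlapped EoVP16, Spearman's rho between the heights was 0.296 and Pearson's r of the log2 heights was 0.423. These coefficients are across peaks, which are not independent replicates, and no p was computed.

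Median EoVP16 height was highest at sites of both factors. EoVP16 peaks that overlapped EoGFP and BraGFP (n = 7040) had a median of 78 fragments, against 59 for those with EoGFP alone (n = 13928), 51 for those with BraGFP alone (n = 2249) and 43 for those with neither (n = 12986). The differences between these medians were not tested, and 3 of the 5 tallest EoVP16 peaks overlapped no EoGFP peak. Among the tallest EoVP16 peaks, 57.6% (56.0 to 59.2) overlapped BraGFP, falling to 10.1% (9.17 to 11.1) among the lowest. In EoV5 the corresponding shares were 28.5% (27.1 to 29.9) and 14.4% (13.3 to 15.5).

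BraGFP peaks with no EoGFP peak were then sought in the other Eomes lists. Of the 6 BraGFP peaks near Msgn1, 4 were of this kind, as were 12 of 12 near Cubn, an endocytic receptor gene, and 12 of 13 near Tcf7l1, a Wnt-pathway repressor. Of the 19505 BraGFP-only peaks, 1438 overlapped EoV5, or 7.37% (7.01 to 7.75), and 2332 overlapped EoVP16, or 12.0% (11.5 to 12.4). The shifted peaks gave 2.45% and 2.28% (permutation p = 0.001, the smallest possible). Either list held 15.1% (14.6 to 15.6) of BraGFP-only peaks, against 95.9% (95.5 to 96.4) of BraGFP peaks shared with EoGFP and 93.4% (93.0 to 93.7) of EoGFP-only peaks.

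At equal list size, with the 13000 widest peaks of each list, EoV5 peaks overlapped EoGFP at 64.9% and BraGFP at 31.5%, a difference of 33.4 points. That difference was 14 points with the 1000 widest peaks, 22.1 with the 5000 widest and 20.5 with EoV5 ranked by fold or pileup. EoVP16 peaks overlapped EoGFP at 63.0% and BraGFP at 35.9%, a difference of 27.2 points. It was 10.2 points with the 1000 widest, 17.5 with the 5000 widest, 15.6 by fold and 15.7 by pileup. Both main differences had p of at most 1e-300 in an exact McNemar test over peaks. BraGFP peaks overlapped EoV5 at 32.1% and EoGFP at 34.0%, a difference of -1.85 points (exact McNemar p = 5.0e-08). This difference was -3.8 with the 1000 widest, -1.38 with the 5000 widest and -5.55 with lists thinned at random. It was -17.5 with EoV5 ranked by fold (16.5% against 34.0%) and -17.6 by pileup. In every ranking by fold or pileup, EoGFP and BraGFP stayed ranked by width, so these values mix 2 rankings. Another 2 differences did not keep their sign. EoV5 overlapped EoGFP more than EoVP16 by 6.23 points (exact McNemar p = 3.5e-37), and by 15.5 points with lists thinned at random. The sign turned with the 1000 widest peaks (-11.7), the 5000 widest (-4.26), or ranking by fold (-3.71) or pileup (-4.01). BraGFP overlapped EoVP16 more than EoGFP by 2.38 points (exact McNemar p = 1.2e-12). This became -0.1 with the 1000 widest peaks and -0.990 with lists thinned at random. Thinning at random removed more peaks from the longer lists, which lowers the overlap with them by itself. In the whole lists, BraGFP overlapped EoVP16 at 34.0% and EoGFP at 29.3%, so the thinned values do not decide any of these signs.

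Peaks gathered at the ends of coding genes. Midpoints within 1 kb of either end of a coding gene made up 27.7% of EoGFP peaks (27.2 to 28.2), 16.1% of BraGFP peaks (15.7 to 16.5), 16.1% of EoV5 peaks (15.7 to 16.4) and 27.9% of EoVP16 peaks (27.4 to 28.4). In the wider 50% of EoGFP and BraGFP the shares were 41.6% and 27.1%. In the taller 50% of EoV5 and EoVP16 they were 11.7% and 36%. These parts were chosen by different measures, so they do not compare BraGFP with EoV5. Shifts gave 3.09% to 3.15% for the 4 lists, with a permutation p of 0.002, the smallest that a two-sided test with 1000 shifts can give. Among classes, 42.9% of shared peaks (41.8 to 43.9), 22.0% of EoGFP-only peaks (21.5 to 22.6) and 5.13% of BraGFP-only peaks (4.83 to 5.45) lay there. BraGFP-only peaks lay elsewhere inside coding genes at 52.4% (51.7 to 53.1), against 38.6% in the shifts (permutation p = 0.002, the smallest possible). EoV5-only peaks lay at gene ends at 2.86% (2.63 to 3.12), against 3.07% in the shifts (permutation p = 0.16). EoVP16-only peaks lay there at 28.3% (27.6 to 29.0).

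The differences between classes were tested after these shares were seen. EoGFP-only exceeded BraGFP-only peaks by 16.9 points (95% interval 16.3 to 17.5), shared exceeded EoGFP-only peaks by 20.8 points (19.6 to 22.0), and EoVP16-only exceeded EoV5-only peaks by 25.5 points (24.7 to 26.2). Fisher's exact p was 5.2e-269 for the second and at most 1e-300 for the others. In the wider 50% of each class the differences grew to 25.9, 24.9 and 43.8 points in the same order, so their sizes depended on peak width. The gene table gives no strand, so an end may be a start or a finish of transcription.

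**Figure D3:**
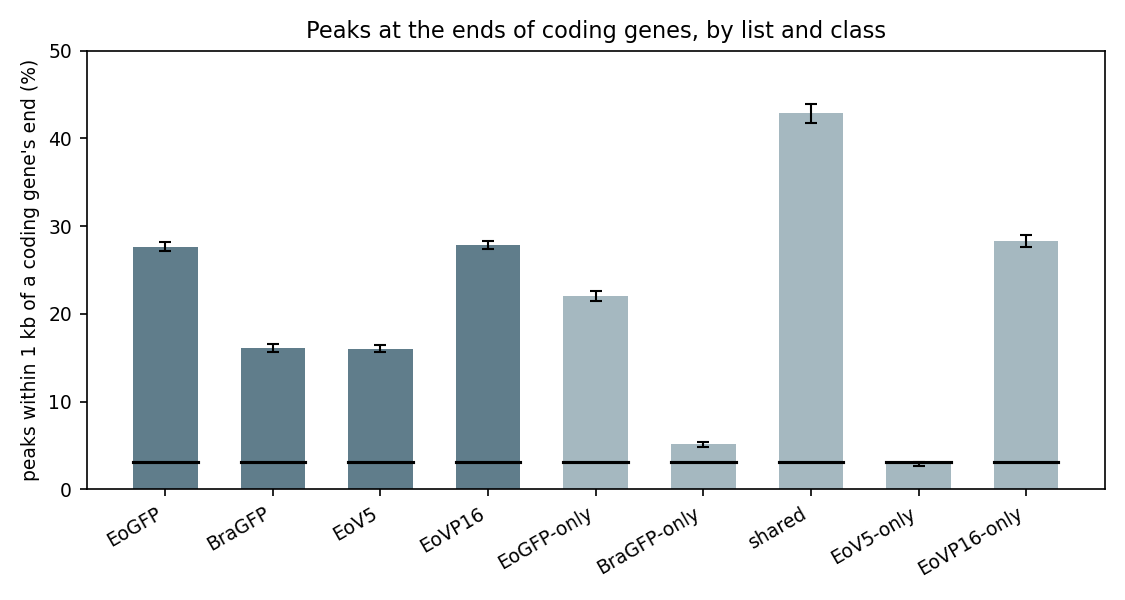
Share of peaks with a midpoint within 1 kb of either end of a coding gene, in percent (y axis), for the 4 lists (dark bars) and 5 classes of peaks (light bars). Error bars are 95% Wilson intervals and black lines are the mean of 1000 shifts; shared peaks stand at 42.9%, BraGFP-only peaks at 5.13% and EoV5-only peaks at 2.86%.

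The gene lists asked which developmental programmes lie near the peaks. All 15 members of the primitive streak, Nodal and Wnt lists had an EoGFP peak within 50 kb, as did all 16 definitive endoderm and all 14 FGF and epithelial-mesenchymal transition genes. For BraGFP, all 16 anterior mesoderm and all 14 FGF genes had a peak. Because 81.1% of all 21887 coding genes had an EoGFP peak and 76.5% a BraGFP peak within 50 kb, such counts could rise little above those of random lists. In the permutation test against 10000 random lists matched on gene territory, 0 of 14 lists passed an adjusted p of 0.05 in any of the 4 peak lists. The unadjusted p was below 0.05 for 6 lists with EoGFP, 2 with BraGFP, 5 with EoV5 and 5 with EoVP16.

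In a window of 10 kb, 3 lists passed for EoGFP. All 15 Nodal genes (9.70 expected), all 15 Wnt genes (9.65) and all 14 epithelial-mesenchymal transition genes (8.91) had a peak, each with an adjusted p of 0.0476 in the permutation test. Counting peaks in place of genes was added after seeing the data, with each peak counted once and random lists that kept neighbouring members together as runs of genes. Nodal genes had 74 EoGFP peaks against 43.2 in such lists (permutation test, adjusted p = 0.0892), 81 EoV5 peaks against 45.8 (0.0892) and 94 EoVP16 peaks against 52.9 (0.0546), so none of these passed. Counted once for each gene and against scattered random genes, the Nodal counts had adjusted p of 0.0252, 0.0286 and 0.0168 in the permutation test. Of the Nodal genes, the receptor genes Acvr2b and Acvr1b had 11 and 9 EoGFP peaks, and Smad7, an inhibitor of the pathway, had 5 EoGFP and 9 BraGFP peaks. Genes of epithelial-mesenchymal transition had 97 EoVP16 peaks against 46.9 (permutation test, adjusted p = 0.0336), with Cdh1 (E-cadherin) at 15 and Zeb2 at 18. Peaks were sought over the whole gene span, and random lists were matched on territory but not on gene length. Zeb2 spans 134 kb and Cdh1 66.9 kb, so gene length may add to this count and to the 3 calls at 10 kb. Hox genes, which pattern the body axis, had 28 BraGFP peaks against 33.8 (permutation test, adjusted p = 0.798). Counted once for each gene and against scattered random genes, they had 97 against 49.0 (permutation test, adjusted p = 0.0084), since neighbouring Hox genes share peaks.

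Near early lineage genes most unshared peaks were EoGFP-only, and near Hox genes most were BraGFP-only. The first majority was not particular to early lineage genes. Coding genes had a mean of 2.09 EoGFP-only and 1.44 BraGFP-only peaks within 50 kb. BraGFP-only peaks made up 47.0% of all unshared peaks. In Fisher's exact test they made up 24.6% near definitive endoderm genes (adjusted p = 0.0046), 25.9% near anterior mesoderm genes (0.0099), 27.4% near primitive streak genes (0.0062), 26.2% near neuroectoderm genes (0.0023), 26.2% near epiblast genes (0.0208) and 30.2% near Wnt genes (0.0087). They made up 71.9% near Hox genes, 23 BraGFP-only against 9 EoGFP-only peaks (Fisher's exact test, adjusted p = 0.0207). Hox genes had few EoGFP peaks and no excess of BraGFP peaks: 14 EoGFP, 13 EoV5 and 27 EoVP16 peaks against 42.3, 45.2 and 51.9 in random runs, a shortfall that was not tested. These 7 of 14 tested lists passed the test, which was two-sided and adjusted over 21 lists. Lists chosen as other cell types or unrelated controls also passed the exact test, with 26.1% near trophoblast genes (adjusted p = 0.0162), 27.5% near photoreceptor genes (0.0346) and 27.9% near housekeeping genes (0.0322). Against random lists that kept neighbouring members together, a test added after seeing the data, 1 of 14 lists passed: Hox, at 71.9% against 41.0% (two-sided permutation test, adjusted p = 0.0210). The 21 Hox genes lie in 4 loci, so this rests on 4 places in the genome. The next lowest adjusted p values of this permutation test were 0.0504 for neuroectoderm and 0.0630 for definitive endoderm. Their random means were 46.0% and 44.7%, and those of primitive streak and anterior mesoderm were 41.3% and 44.0%.

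**Figure D4:**
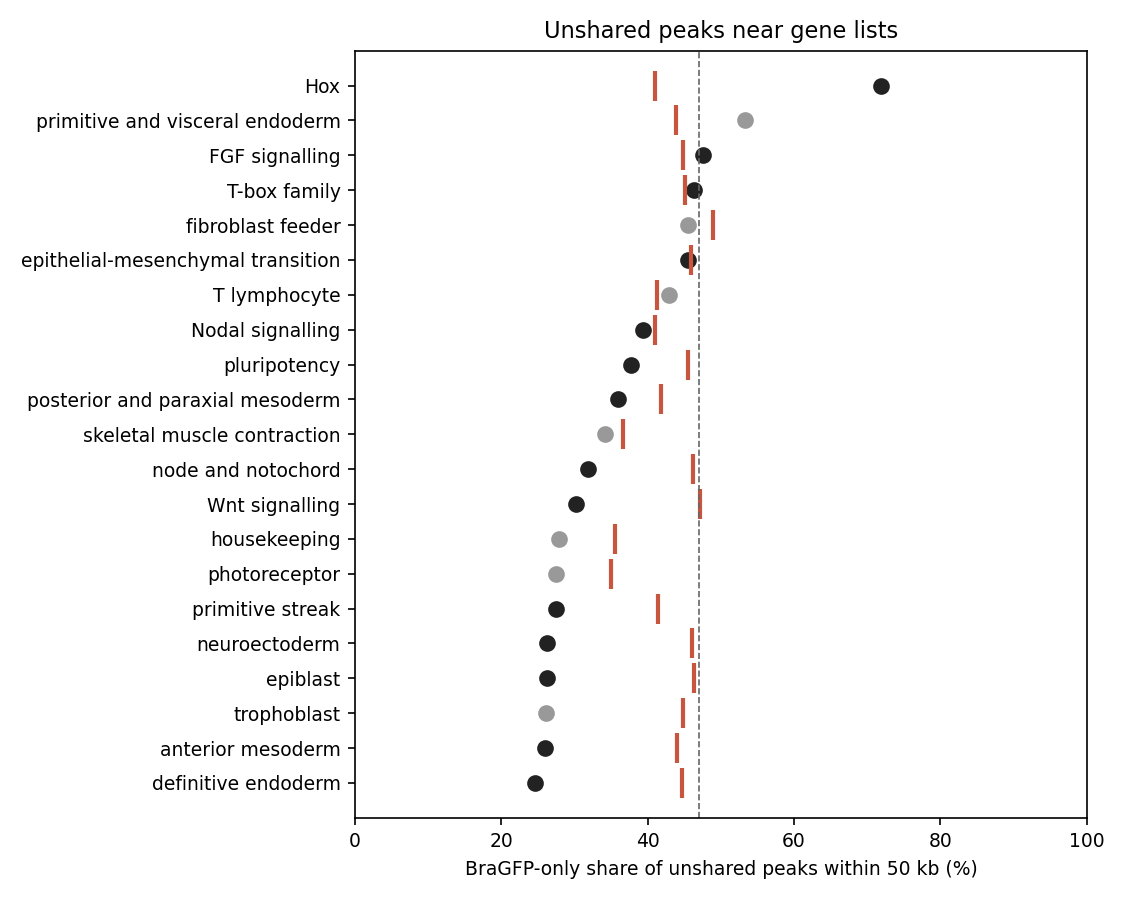
BraGFP-only share of the EoGFP-only and BraGFP-only peaks within 50 kb of each gene list, each peak counted once, in percent (x axis), for 14 tested lists (black points) and 7 other lists (grey points). Red bars are the mean of 10000 random lists that keep neighbouring members together and the dashed line is the 47.0% of all unshared peaks; Hox, with 4 loci, stands at 71.9% against 41.0%.

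Members of these lists showed the range. Nes, an intermediate filament gene of neural progenitors, had 10 EoGFP and 2 BraGFP peaks within 50 kb, Lef1 had 10 and 3, and Wnt3a, a Wnt ligand of the posterior streak, had 9 and 2. The endoderm factors Gata6 and Hnf4a had 6 and 7 EoGFP peaks and 3 and 6 BraGFP peaks. Noto, a homeobox gene of the notochord, had 7 and 2. In the other direction, Tcf7l1 had 6 EoGFP and 13 BraGFP peaks, and Irx3, a homeobox gene of the neural plate, had 3 and 5. Lhx1 (5 and 5) and Cdh2, the N-cadherin gene (9 and 10), had similar counts. Named after their values were seen, Gsc, Mixl1, Evx1 and Tdgf1 were the 4 primitive streak genes with an EoGFP and no BraGFP peak. Hand2 and Tbx3 were the 2 anterior mesoderm genes with a BraGFP and no EoGFP peak. The other Eomes lists did hold peaks there, 1 EoV5 and 2 EoVP16 peaks at Hand2 and 2 of each at Tbx3.

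Within the spans of the 4 Hox clusters lay 6 EoGFP, 18 BraGFP, 8 EoV5 and 16 EoVP16 peaks, of which 4 were EoGFP-only and 16 BraGFP-only. The Hoxa cluster (chromosome 6) held 7 BraGFP and 0 EoGFP peaks. These included a BraGFP peak at Hoxa2 (52163801 to 52166125) and others in the annotated span of Hoxa3. The Hoxb cluster (chromosome 11, 96194316 to 96368254) held 5 BraGFP peaks, between 96311373 and 96350437, and 1 EoGFP peak near Hoxb13. The Hoxd cluster (chromosome 2, 74668225 to 74765142) held 5 EoGFP and 6 BraGFP peaks, and the Hoxc cluster (chromosome 15, 102921131 to 103036856) held 0 of either. The Hox call ended with a window of 100 kb, where the share was 63.6% (Fisher's exact test, adjusted p = 0.101). It also ended when EoGFP-only peaks were limited to those in EoV5 or EoVP16 and BraGFP-only peaks to those in neither (69.6%, Fisher's exact test, adjusted p = 0.0526).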

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

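Of the tests in this part, the differences of location between classes, the overlap of BraGFP-only peaks with EoV5 as a test of random calls, the EoV5 pileup of BraGFP-only peaks, the random runs and the binomial tests of the Hox clusters were chosen after the results were seen.

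Each result here is a tested difference between groups of peaks. The share of peaks within 1 kb of a coding gene's end differed by 16.9 points between EoGFP-only and BraGFP-only peaks, and by 20.8 points between shared and EoGFP-only peaks. It differed by 25.5 points between EoVP16-only and EoV5-only peaks. Near Hox genes, BraGFP-only peaks were 71.9% of the unshared peaks, against 47.0% in all.

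BraGFP-only peaks numbered 19505 and lay at gene ends less often than EoGFP-only peaks. Calls at random positions are argued against as the whole cause, since 5.13% lay at gene ends, above the highest of 1000 shifts (3.52%), and 7.37% overlapped EoV5 (highest shift 2.83%). BraGFP-only peaks found in EoV5 had a median EoV5 pileup of 87 fragments, against 113 for BraGFP peaks shared with EoGFP, but EoV5 peaks without EoGFP were also lower where BraGFP was absent (79 against 130), so this decides nothing. Eomes sites too weak for the EoGFP minimum pileup and Brachyury sites that Eomes does not bind therefore cannot be told apart, as the different minimum pileups cannot be removed with these files.

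At the Hox genes, the share was high with few EoGFP peaks (14 against 42.3 in random runs) and no excess of BraGFP peaks (28 against 33.8). Of the clusters, 3 held more BraGFP-only than EoGFP-only peaks, by 7 to 0 in Hoxa (exact binomial p = 0.0051), 5 to 1 in Hoxb (0.106) and 4 to 3 in Hoxd (0.713), so 1 cluster carrying the difference stays open. The binomial test takes the peaks of a cluster as independent, which neighbouring peaks are not, and its p values were not adjusted over the clusters. Eomes sites of the Hox clusters left out by the EoGFP minimum pileup could account for some: 30.4% of the 23 BraGFP-only peaks near Hox genes lay in EoV5 or EoVP16, against 15.1% elsewhere (Fisher's exact p = 0.0711). With 7 such peaks, this explanation and Brachyury-specific binding cannot be told apart.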

How the results depend on the processing

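For 55 results, alternatives left 144 values on the same side of the threshold or near the value reported, 25 moved, 8 passed the threshold or rose in count, 25 no longer passed or fell in count, and 10 changed direction. The 8 overlap shares tested under other rules kept a permutation p of 0.001, the smallest possible, under every alternative run. With both lists cut to the wider or taller 50%, EoGFP in EoV5 was 50.3%, EoV5 in EoGFP 38.9% and BraGFP in EoGFP 35.0%. A cut of the partner list lowers such shares by itself. The wider 50% of BraGFP overlapped the whole EoGFP list at 44.6%. The 25 that moved are peak counts near single genes in other windows or in the wider 50% of a list. The EoV5 difference (EoGFP minus EoVP16) became -11.7 points at 1000 peaks, -4.26 at 5000, -3.71 ranked by fold and -4.01 ranked by pileup, but 15.5 with random thinning. The BraGFP difference (EoVP16 minus EoGFP) became -0.1 at 1000 peaks (exact McNemar p = 1) and -0.990 with random thinning. Random thinning removed more peaks from the longer lists, so the thinned values do not decide the sign of either difference. The EoGFP width difference became -17 fragments as EoV5 pileup, the FGF share 45.6% at 100 kb, and the T-box share 45.7%, against 45.2% in random lists, or 46.3%, against 45.1% in random runs. Gene lists near EoGFP peaks rose from 0 to 3 in a 10 kb window and to 1 by number of peaks. By number of peaks BraGFP (Hox) and EoV5 also rose to 1 and EoVP16 to 2, but with peaks counted once and random runs of neighbouring genes the counts were 0, 0 and 1, and 0 for EoGFP. The 7 lists that differed between EoGFP and BraGFP fell to 3 in the wider 50% of each list and to 1 against matched random lists or random runs. They were 5 at 100 kb, where node and notochord newly passed (Fisher's exact test, adjusted p = 0.0406). Limited to peaks held or not held by the other Eomes lists they were also 5, and posterior and paraxial mesoderm newly passed (Fisher's exact test, adjusted p = 0.0442). Both counts of 5 are among the 144. For all of these, the cause was not tested. Ranking by pileup, thinning, EoV5 pileup, numbers of peaks, random runs, matched random lists for the difference and all alternatives for single genes were chosen after seeing the data. No paired analysis was possible because each construct has 1 peak list, from 1 library or from 2 joined, so columns carry no replicate numbers, and leaving out 1 replicate at a time was not possible for the same reason. The planned motif and half-site alternatives were not run, since no genome sequence was used here. Depth is unknown, and peaks under each minimum pileup cannot be seen.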

Other observations

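The tests of EoV5 against EoVP16 at gene lists and the division of these lists by height were chosen after the data were seen.

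EoVP16-only peaks made up 46.5% of the unshared peaks of EoV5 and EoVP16. They made up 72.6% near neuroectoderm genes (Fisher's exact test, adjusted p = 5.7e-04), 80.0% near Hox genes (0.0049), 67.1% near posterior and paraxial mesoderm genes (0.0047), 63.9% near genes of epithelial-mesenchymal transition (0.0177) and 64.4% near primitive streak genes (0.0295). Near definitive endoderm genes they made up 29.8% (0.0301), 17 EoVP16-only against 40 EoV5-only peaks. Housekeeping genes stood at 82.2% (2.7e-05) and skeletal muscle genes at 67.5% (0.0301). Against territory-matched random lists, 0 of 21 lists passed, with neuroectoderm (adjusted p = 0.126) and definitive endoderm (0.128) lowest, and an unadjusted permutation p of 0.0060 and 0.0122.

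Of the tallest 3819 EoV5 peaks, 5.37% lay within 1 kb of a gene end, against 19.4% of the lowest 3820 and a mean of 3.09% for the whole list in the shifts. In EoVP16 the shares were 27.9% of the tallest 3620, 40.4% of the next 3620 and 13.9% of the lowest 3621. The tallest EoV5 peak (3296 fragments, 95% Poisson interval 3184 to 3410) lay at chromosome 12, 31084098 to 31085668, in GRCm38, 4943 bp from Fam110c. The tallest EoVP16 peak (1379 fragments, 1307 to 1454) lay at chromosome 15, 27741377 to 27742841, inside Trio. Of the tallest 3620 EoVP16 peaks, 88.3% overlapped EoGFP peaks. The tallest EoV5 and EoVP16 peaks did, but the next 3 EoVP16 peaks by height (1212, 1007 and 980 fragments, nearest to Raet1d, Lrrc8b and Gm38702) overlapped none. These genes were chosen after their values were seen.

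The X chromosome held few peaks in all 4 lists, a pattern noticed in the data. Its peaks per Mb were 0.160 times those of the autosomes in EoGFP, 0.189 in BraGFP, 0.243 in EoV5 and 0.220 in EoVP16. Fewer genes per Mb are argued against as the whole cause, since peaks per coding gene were at most 0.364 times those of the autosomes. A single X copy would make peaks lower on the X, and EoV5 argues against it as the whole cause: X density at the minimum pileup was 0.647 times the autosomal density at the doubled minimum (0.496 to 0.719 over single autosomes). In EoVP16 that ratio was 0.840 (0.598 to 1.08), which a single X copy could give. A part of the deficit may therefore come from a single X copy. The ratios at the doubled minimum were per Mb, not per coding gene, so each explanation was tested alone. A single X copy acting together with fewer genes per Mb was not tested and stays open as the cause of the whole deficit. No biological explanation was tested.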
